A study of Homo sapiens with 6 samples.

How the data were processed

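6 RNA samples of EoL-1 cells were measured by RNA-seq, 3 labelled JUN knockout and 3 labelled ATF3/JUN double knockout. The labels' protocols give CRISPR/Cas9 editing, polyA RNA extracted with phenol and chloroform, and a stranded mRNA library kit from Illumina. The guide sequences, the edited alleles and the read layout are not given in the sources used here, and no unedited sample was among those analysed. The labels do not say whether the 3 libraries of a group came from separate clones or from repeat cultures, while the names of the deposited files carry a different clone code for each library of a group. As nothing states that they were separate cultures, p-values measure only the spread between these libraries.

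Per the submitters' processing notes, the tools were FastQC 0.11.9 and Salmon 1.6.0 with the build hg38. Salmon assigns reads to transcripts and shares out reads that fit several of them. The deposited files hold an estimated count and a TPM value (transcript abundance scaled for length and library size) for each of 177456 Ensembl transcripts per library, per the file headers. The effective length was 250 bases below the transcript length for the median transcript longer than 1000 bases and was identical in all 6 files. The transcript set behind the deposited values held almost no long non-coding RNA: 23 of the genes matched here were annotated as lincRNA.

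Transcripts were joined to GENCODE release 29 (GRCh38) by Ensembl identifier without its version. Of the 177456 transcripts, 167027 (94.1%) matched, in 35052 genes. The other 10429 carried 3.58% to 3.71% of the estimated reads of a library and were left out of the gene table. Their sequences were not used here, and they can include alternative copies of regions such as the major histocompatibility complex, so a gene with such a copy may have only part of its reads counted. Gene symbols were updated to current names where the reference table gave one. Estimated counts were summed per gene and rounded to whole numbers. The totals were 26146998 to 29567970 estimated reads per library. Library pairs were compared by a chi-square of their counts over genes. The closest pair, double knockout replicates 1 and 2, gave 12.5 per gene, far above the value of about 1 that sampling noise alone gives. No pair thus looked like the same library counted again, and all 6 were kept. This check cannot show that they were separate cultures.

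The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with filterByExpr, TMM scaling and robust dispersion, two-sided, with the group as its single term and Benjamini-Hochberg adjustment at 0.05. It kept 12954 genes. The log2 fold change is double knockout minus JUN knockout, and its standard error (SE) is its size divided by the square root of F. CPM (the count scaled to a common library total) was computed after TMM scaling. Gene lists were tested with camera (limma 3.58.1) at the preset inter-gene correlation of 0.01, for lists with at least 5 tested members. Of 27 lists with 711 entries fixed before the data were examined, 26 qualified. 6 list entries had no match in the gene table. Single values were compared by exact two-sided permutation of the 6 libraries, which cannot give a p below 0.1.

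The replicate numbers were taken as pairing the groups, because the names of the deposited files give same-numbered libraries of both groups the same clone code. The labels themselves do not state it. The deviations from the group means correlated at 0.33, 0.096 and 0.41 for numbers 1, 2 and 3, so the values by themselves leave number 2 just under the limit of 0.1 used for this check, and double knockout replicate 2 correlated slightly more with JUN knockout replicate 1 (0.11). The main test stayed without the pairing, as fixed beforehand, and a fit with the replicate number as a block was run beside it.

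Named genes followed a rule fixed beforehand. ATF3 and JUN were always named, and since under 10 genes passed, the 6 lowest p-values in each direction among genes with a symbol and a mean of at least 1 CPM were named as not passing. In each list without a passing member, the member with the highest mean CPM was named. Genes named outside this rule are marked as such.

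The procedure was tested on simulated counts with the means, spreads and library sizes of these libraries. In 3 runs of the double knockout against JUN knockout comparison, each with 200 of 12954 genes changed, edgeR recovered 23.9% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 94.4% of those changed 4-fold. Of its calls, 6.2% were false. DESeq2 recovered 50.2%, 80.1% and 97% at these folds, with 23% of its calls false. Simulated genes varied independently of each other. Camera called a list of 26 genes lowered by 0.3 on the log2 scale in 5 of 5 runs and none of 125 unchanged lists. As these genes were independent, the runs could not test false calls of lists whose members move together.

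Alternatives fixed beforehand were RLE and upper-quartile factors, library totals alone, DESeq2 1.42.0, limma-voom, 2 other low-count filters, an average transcript length offset, protein-coding genes alone, the replicate block in edgeR and DESeq2, leaving out each library or each same-numbered pair, camera with an estimated correlation, and fry. Sums over transcripts annotated as protein-coding were added after the data were seen, as were list tests without each pair. Transcript types (protein-coding, retained intron, nonsense-mediated decay) were taken from GENCODE release 29. Similar transcripts of other genes were searched with blastn 2.17.0. All 10 splits of the 6 libraries into 3 and 3 were also fitted, and for the G2/M list the 10 splits of the 5 libraries left without double knockout replicate 3.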

Results

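EoL-1 is an established human line from an eosinophilic leukaemia, and the labels call its cell type eosinophil. JUN and ATF3 are transcription factors with a basic leucine zipper, and they can pair with each other to bind DNA. The series held 3 libraries from cells labelled JUN knockout and 3 from cells labelled ATF3/JUN double knockout. The comparison therefore asked what loss of ATF3 added to loss of JUN, and it could not show what loss of JUN itself did. The JUN knockout libraries held 27489269, 29032697 and 27344031 estimated reads and the double knockout libraries 26146998, 27081713 and 29567970. Spearman correlations of log2 CPM between libraries, across genes, lay between 0.979 and 0.994.

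The targeted genes were examined first. ATF3 (ENSG00000162772) lies on chromosome 1 at 212565334 to 212620777, plus strand, in GRCh38. Its mRNA was at 14.3 ± 5.68 CPM in the JUN knockout and 10.2 ± 2.72 CPM in the double knockout (SD, n = 3 each). It was lower in the double knockout in 3 of 3 same-numbered pairs, at 20.2 and 13.1, 13.7 and 10.0, and 8.89 and 7.63 CPM. The log2 fold change was −0.48 (SE 0.32), which edgeR did not separate from 0 (adjusted p = 0.931). Among ATF3 transcripts, ATF3-202 carried 67.7% of the reads, at 6.64, 4.53 and 3.45 TPM in the JUN knockout and 3.63, 4.48 and 2.95 TPM in the double knockout. JUN (ENSG00000177606, chromosome 1, 58780788 to 58784327, minus strand) was at 21.7 ± 7.42 and 18.7 ± 6.21 CPM, a log2 fold change of −0.21 (SE 0.32, edgeR adjusted p = 0.97). Exact permutation of the CPM gave p = 0.4 for ATF3 and p = 0.8 for JUN. With the pairing, edgeR gave ATF3 a log2 fold change of −0.44 (unadjusted p = 0.00988, adjusted p = 0.394 over all genes), while exact sign flips of its 3 pair differences gave p = 0.25, the smallest that 3 pairs allow. A frameshift need not lower the mRNA that carries it, and no unedited library was present, so these levels did not check either edit. The 15 tested genes within 1 Mb of ATF3 had a median log2 fold change of 0.0025, and the 3 within 1 Mb of JUN had one of −0.18.

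**Figure D1:**
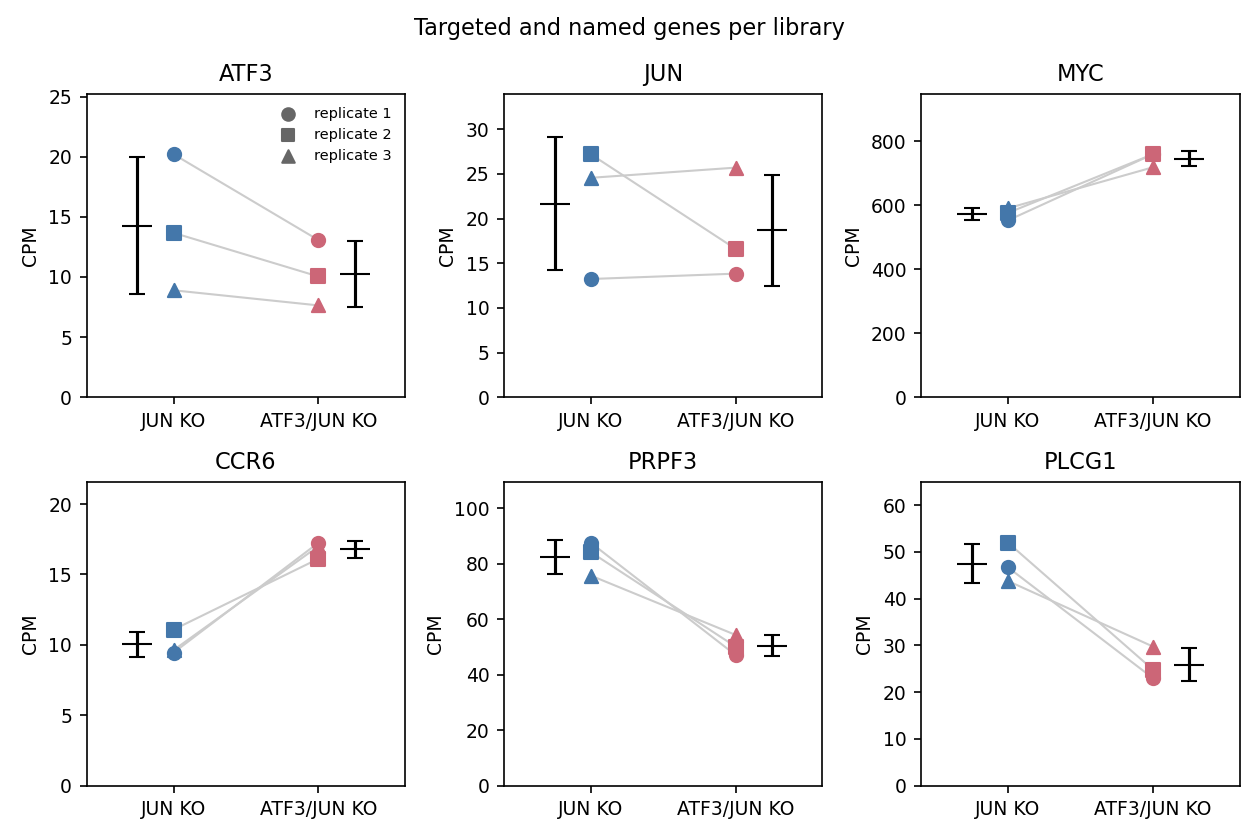
Expression in CPM of ATF3, JUN and 4 genes named by the fixed rule in each library (points, with shapes for replicate numbers and grey lines joining same-numbered libraries) and the mean ± SD of the 3 libraries of a group (black). ATF3 and JUN overlapped between the groups. MYC, CCR6, PRPF3 and PLCG1 did not, but they were picked for a low p in these libraries, which favours such a separation. Of all tested genes 12.3% did not overlap, where chance gives 10%, and no gene passed the main test.

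Among genes with a symbol and a mean of at least 1 CPM, and with TRIM26 set aside, the differences with the lowest p-values were modest. Among the genes higher in the double knockout, MYC, the growth-promoting transcription factor, was at 573 ± 19.1 CPM in the JUN knockout and 745 ± 23.5 CPM in the double knockout (SD, n = 3 each; log2 fold change 0.38, SE 0.07). CCR6, the receptor for the chemokine CCL20, was at 10.0 ± 0.898 and 16.8 ± 0.599 CPM (0.74, SE 0.11), and MUC1, a membrane mucin, at 3.12 ± 0.23 and 6.13 ± 0.422 CPM (0.97, SE 0.16). SPN, which encodes the leukocyte sialoglycoprotein CD43, AP5B1, a subunit of an adaptor complex of endosomes, and SLC38A10, of an amino acid transporter family, had log2 fold changes of 0.61, 0.53 and 0.46. Among the genes lower in the double knockout were PRPF3, a component of the spliceosome (82.4 ± 6.09 and 50.5 ± 3.64 CPM; −0.71, SE 0.09), and PRPF39, a factor of pre-mRNA splicing (106 ± 2.2 and 71.1 ± 5.56 CPM; −0.57, SE 0.08). PLCG1, a phospholipase of receptor signalling, was at 47.5 ± 4.15 and 25.9 ± 3.5 CPM (−0.88, SE 0.12). PIF1, a DNA helicase, and CLASRP, an arginine- and serine-rich protein, had log2 fold changes of −0.71 and −0.56. Each of these 11 genes moved the same way in 3 of 3 pairs, as did 33.2% of all tested genes (25% by chance), and genes picked by their p would mostly do so.

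None of them passed the main test. edgeR called 0 of 12954 genes, with 753 at an unadjusted p under 0.05 and a lowest adjusted p of 0.397. With the pairing it also called 0, with 1268 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0873. DESeq2 called 71 genes (30 higher, 41 lower), and limma-voom called 4 that were all among the 71. Of the 71, 8 had an absolute log2 fold change of at least 1. These included the 5 genes described below that were at 0 in 1 group. The 11 genes above were among the DESeq2 calls, with adjusted p from 9.06e-08 for AP5B1 to 0.00191 for MUC1. Groups did not overlap in 12.3% of tested genes, where chance gives 10%. In simulated libraries of this size, with 200 genes changed per run, edgeR recovered 70.1% of genes changed 2-fold but 23.9% of those changed 1.5-fold. With fewer genes changed the adjusted threshold is stricter, so these shares can overstate what would be found here.

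TRIM26, a gene of the major histocompatibility complex (chromosome 6, 30184455 to 30213427), had the lowest p of the genes lower in the double knockout and is uncertain. It had 87, 127 and 59 estimated reads in the JUN knockout and 0 in each double knockout library, at least 29.5-fold lower against a floor of 3 counts per library. It was the 1 gene that edgeR called when no low-count filter was used (adjusted p = 0.0402). The complex varies between people and has alternative haplotypes in the reference assembly. A search of GENCODE transcripts found no similar one of another gene, and no single partner was found among 101 unmatched transcripts of similar length. The sequences of unmatched transcripts were not searched, and reads spread over several copies were not looked for. A loss of its reads to alternative copies was therefore not shown and could not be excluded. Another 4 genes, chosen after their values were seen, were also at 0 in 1 group: RIMBP3B in the double knockout, and MAFIP, KIAA1143P1 and ENSG00000255432 in the JUN knockout. RIMBP3B has a near-identical copy, RIMBP3C, KIAA1143P1 is a processed pseudogene, and MAFIP lies on the scaffold GL000194.1 outside the assembled chromosomes, so these are uncertain too. ENSG00000255432 and MAFIP had edgeR p-values among the lowest of all genes. TRIM26, RIMBP3B, MAFIP and ENSG00000255432 were the 4 limma-voom calls.

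Genes of the G2 and M phases of the cell cycle were lower as a set in the double knockout. Of 26 members, 24 had a log2 fold change below 0, with a median of −0.20 (camera adjusted p = 8.65e-11). With an estimated correlation the adjusted p was 0.447. In edgeR no member passed over all genes or adjusted over the list alone, while DESeq2 called PLK1 (adjusted p = 0.0212). Other splits of the libraries also gave low values for this list: in a permutation of the labels, 6 of the 9 other splits had an unadjusted camera p under 0.05, the lowest 2.76e-08, against 3.33e-12 for the real one. PLK1, a mitotic kinase, was at 138 ± 5.03 CPM in the JUN knockout and 114 ± 1.23 CPM in the double knockout (SD, n = 3 each). CENPF, a kinetochore protein, was at 433 ± 34.0 and 354 ± 30.3 CPM, and both examples were picked by p-value after it was seen. TOP2A, the most abundant member, went the other way at 647 ± 38.0 and 686 ± 117 CPM, though its log2 fold change of 0.08 turned to −0.02 with a transcript length offset. The median over members was −0.11, −0.10 and −0.35 in pairs 1, 2 and 3, and without double knockout replicate 3 the list's median was −0.125 (adjusted p = 0.00151). The G1/S and replication list was also lower (23 of 26 members below 0, median −0.07, camera adjusted p = 0.0404, and 0.666 with an estimated correlation). That call was lost without JUN knockout replicate 2 or 3 or double knockout replicate 2, and without double knockout replicate 3 the direction turned (adjusted p = 0.763). The median was −0.171 without double knockout replicate 1. Its most abundant member MCM4, a subunit of the replicative helicase, was at 625 ± 118 and 628 ± 21.0 CPM.

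Several lists of signalling and myeloid genes were higher as sets, by small amounts. JAK-STAT target genes were above 0 in 18 of 19 members (median 0.12, camera adjusted p = 0.00844, and 0.447 with an estimated correlation). PIM1, a kinase gene induced by STAT5, was at 710 ± 195 and 967 ± 295 CPM. This list was the 1 that fry called with the pairing (adjusted p = 0.0419). Its camera call was lost without JUN knockout replicate 3 or double knockout replicate 1 (highest adjusted p = 0.0577), and its median was 0.073 without the latter. Immediate early and MAPK feedback genes were above 0 in 18 of 25 members (median 0.10, adjusted p = 0.0268, and 0.562 with an estimated correlation), and MYC passed when adjusted over the list alone. AP-1 and related factors, the family of the targeted genes, were above 0 in 19 of 27 (median 0.08, adjusted p = 0.0421, and 0.652 with an estimated correlation). ATF4, the most abundant, was at 646 ± 81.4 and 620 ± 121 CPM. Growth factor and cytokine receptors were above 0 in 19 of 25 (median 0.12, adjusted p = 0.0268, and 0.447 with an estimated correlation), with IL17RA at 253 ± 14.5 and 275 ± 16.1 CPM. Each of the last 3 lists lost its call without JUN knockout replicate 3. The immediate early list also lost it without double knockout replicate 1, the AP-1 list without double knockout replicates 1 or 2, and the receptor list without double knockout replicates 2 or 3 (highest adjusted p = 0.425 for each). Their medians ran from 0.0407 (without double knockout replicate 1) to 0.241 (without JUN knockout replicate 1) for the immediate early list, and from 0.0249 (without double knockout replicate 1) to 0.156 (without double knockout replicate 3) for the AP-1 list. The receptor list's median was 0.0356 without JUN knockout replicate 3, and the immediate early median 0.0384 without both replicates 3 (adjusted p = 0.0574).

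Neutrophil granule and maturation genes were above 0 in 7 of 10 tested members (median 0.28, camera adjusted p = 0.00844, and 0.447 with an estimated correlation). The serine protease gene PRSS57 was at 462 ± 64.4 CPM in the JUN knockout and 638 ± 96.1 CPM in the double knockout. CSF3R, the receptor for granulocyte colony-stimulating factor, passed when adjusted over the list alone (25.7 ± 0.746 and 39.0 ± 7.26 CPM). It was named outside the fixed rule, after its p was seen. Eosinophil genes were above 0 in 10 of 13 (median 0.08, adjusted p = 0.0421, and 0.447 with an estimated correlation). CAT, which encodes catalase and is expressed in most cell types, was the most abundant of them at 189 ± 23.8 and 250 ± 28.8 CPM. Pair medians of the neutrophil list were 0.84, −0.28 and 0.22, and those of the eosinophil list 0.47, −0.05 and 0.11. The calls were lost without JUN knockout replicate 1 or double knockout replicate 1, and the eosinophil call also without double knockout replicate 3 (highest adjusted p = 0.237 and 0.403). The neutrophil median was 0.049 without JUN knockout replicate 1, 0.0746 without double knockout replicate 1, 0.488 without JUN knockout replicate 3, and 0.0151 with no low-count filter (adjusted p = 0.0563). The eosinophil median ran from 0.0357 without double knockout replicate 1 to 0.342 without JUN knockout replicate 3. Without both replicates 1 the medians were 0.00374 for the neutrophil list (adjusted p = 0.407) and 0.0184 for the eosinophil list (adjusted p = 0.712).

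Type I interferon response genes were above 0 in 18 of 26 members (median 0.14, camera adjusted p = 0.0377, and 0.666 with an estimated correlation), with XAF1 at 229 ± 47.1 and 238 ± 52.8 CPM. MHC class I presentation genes were above 0 in 9 of 11 (median 0.15, adjusted p = 0.0268, and 0.645 with an estimated correlation). B2M, the light chain of MHC class I, was at 472 ± 21.1 and 528 ± 17.9 CPM. Members of that list inside the complex can share reads with alternative copies. Both calls were lost without JUN knockout replicate 3, double knockout replicate 1 or double knockout replicate 2 (highest adjusted p = 0.34 and 0.29), while the medians were up to 0.307 (without JUN knockout replicate 1) and 0.262 (without double knockout replicate 3). Without both replicates 2 the MHC class I median was 0.0463 (adjusted p = 0.391) and the interferon median 0.134 (adjusted p = 0.0888). Genes of the unfolded protein response were above 0 in 14 of 19 (median 0.10, adjusted p = 0.0268, and 0.447 with an estimated correlation), with XBP1 at 575 ± 46.6 and 696 ± 92.8 CPM. That call was lost without JUN knockout replicate 1, double knockout replicate 1 or double knockout replicate 3 (highest adjusted p = 0.126), and the median ran from 0.038 without JUN knockout replicate 1 to 0.198 without JUN knockout replicate 3. Without both replicates 1 it was 0.0412 (adjusted p = 0.187). Cholesterol synthesis and uptake genes were above 0 in 20 of 24 (median 0.20, adjusted p = 0.00871, and 0.666 with an estimated correlation). INSIG1, the most abundant, was at 798 ± 236 and 782 ± 210 CPM. The cholesterol call was lost without double knockout replicate 3 (median 0.0603, adjusted p = 0.463), and its direction turned without JUN knockout replicate 1 (−0.0752, adjusted p = 0.216) or both replicates 1 (−0.0452, adjusted p = 0.5). The 13 mitochondrially encoded genes were all below 0 (median −0.19, adjusted p = 0.00844, and 0.666 with an estimated correlation), with MT-CO1 at 16050 ± 3260 and 14930 ± 1760 CPM. Their share of reads was 5.52 ± 1.0% and 4.96 ± 0.641% (exact permutation p = 0.4). Their pair medians were 0.10, −0.39 and −0.16. That call was lost without JUN knockout replicates 2 or 3 or double knockout replicates 1 or 2 (highest adjusted p = 0.425), and the median ran from −0.315 without JUN knockout replicate 1 to −0.0574 without JUN knockout replicate 3. Without both replicates 2 it was −0.0684 (adjusted p = 0.462).

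**Figure D2:**
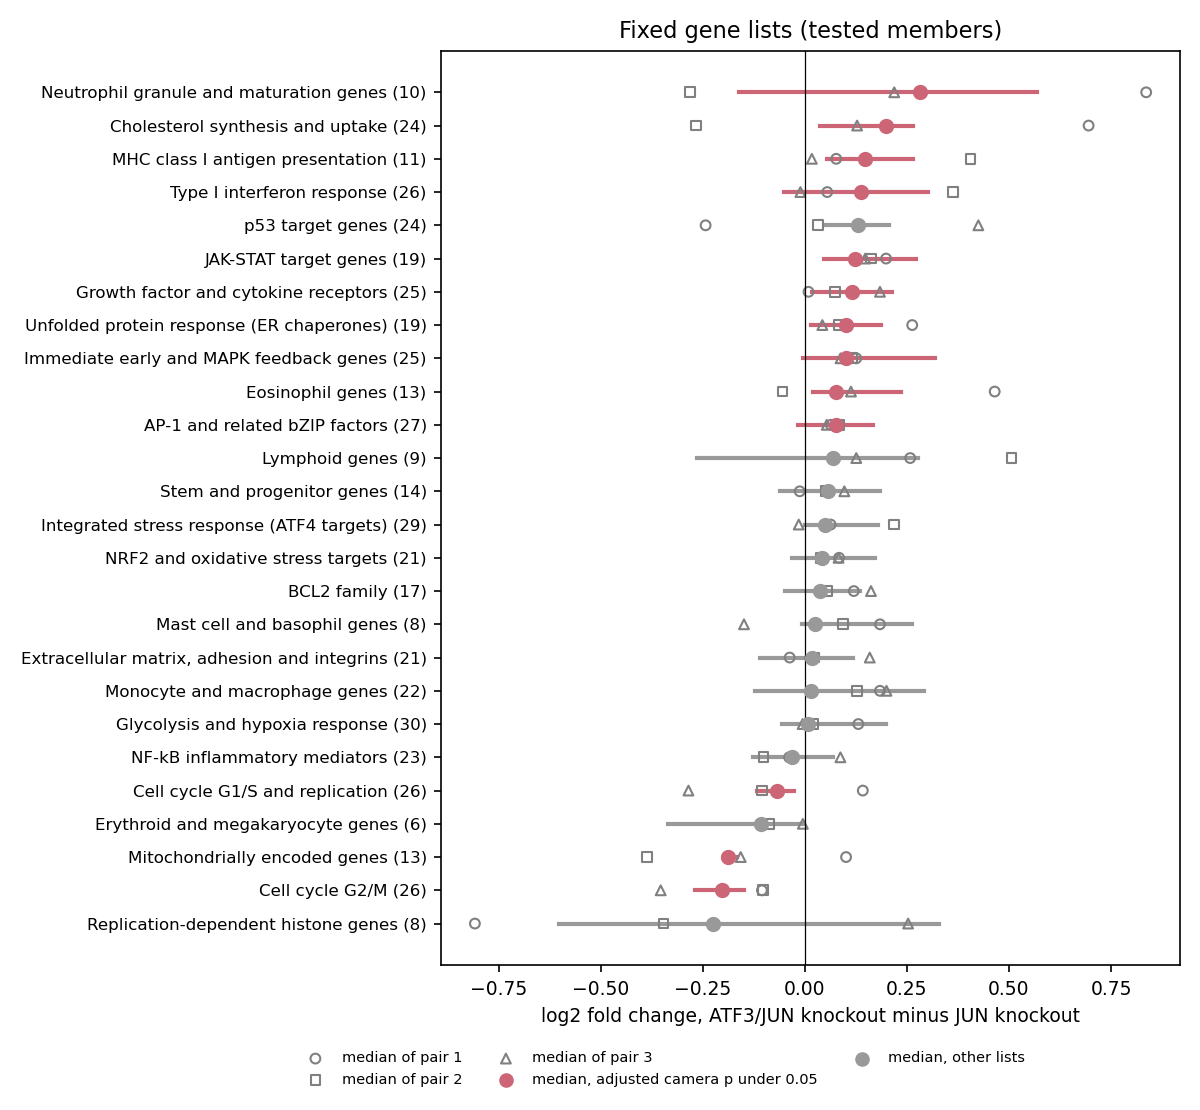
Median log2 fold change (double knockout minus JUN knockout, filled points) with the interquartile range of members (bars) for the 26 tested gene lists, and the median in each same-numbered pair (open shapes). Of the 13 lists past camera (red), the G2/M list had the lowest adjusted p, and the cholesterol and neutrophil lists were among those with pair medians on both sides of 0.

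Camera called 13 of the 26 lists, 10 higher and 3 lower, and 0 with an estimated correlation (lowest adjusted p = 0.447). In each other split of the 6 libraries into 3 and 3, camera at the preset correlation called 5 to 9 lists. With the pairing it called 15, keeping all 13 in the same direction and adding the monocyte and macrophage list and the integrated stress response list, each at an adjusted p of 0.0244. With the pairing and an estimated correlation these 2 had adjusted p of 0.442 and 0.732. Of the 13, 7 stayed past with a transcript length offset and 7 with no low-count filter. The immediate early, eosinophil, receptor and G1/S lists lost their call in both, the AP-1 and interferon lists with the offset, and the neutrophil and MHC class I lists with no filter. Without the pairing the monocyte and stress response lists had adjusted p of 0.127 and 0.418 (0.447 and 0.84 with an estimated correlation) and medians of 0.02 and 0.05. LYZ, the lysozyme gene, was at 284 ± 158 and 260 ± 152 CPM, and SLC7A5, an amino acid transporter gene, at 1263 ± 288 and 1313 ± 334 CPM. The monocyte list also passed with a filter of 1 CPM in 3 libraries (median 0.0436, adjusted p = 0.035), and without JUN knockout replicate 2 (adjusted p = 0.0306) or double knockout replicate 1 (0.0158). Its median ran from 0.000991 without double knockout replicate 3 to 0.17 without double knockout replicate 1. The stress response list passed without JUN knockout replicate 1 (0.000958) or double knockout replicate 3 (4.61e-05), and its direction turned without JUN knockout replicate 3 or double knockout replicate 1 (−0.118 and −0.148).

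The other 11 tested lists did not pass with or without the pairing. The p53 target list (median 0.13, adjusted p = 0.0765) had TNFRSF10B at 217 ± 29.5 and 226 ± 18.4 CPM, and the histone list (−0.22, adjusted p = 0.16) had H1-2 at 1.92 ± 0.243 and 1.80 ± 0.112 CPM. Glycolysis and hypoxia genes (0.01) and NRF2 targets (0.04), both at an adjusted p of 0.176, had GAPDH at 3189 ± 337 and 3204 ± 136 CPM and FTL at 1380 ± 303 and 1407 ± 203 CPM. For the BCL2 family (0.04, adjusted p = 0.205), BCL2 was at 249 ± 64.9 and 309 ± 66.3 CPM, and for stem and progenitor genes (0.06, adjusted p = 0.304), MYB was at 460 ± 9.44 and 488 ± 31.0 CPM. The lymphoid list (0.07, adjusted p = 0.504) had NKG7 at 87.1 ± 4.26 and 105 ± 8.92 CPM, and the mast cell and basophil list (0.02, adjusted p = 0.539) had LMO4 at 47.4 ± 3.95 and 47.8 ± 8.41 CPM. NF-kB mediators (−0.03, adjusted p = 0.598) had SOD2 at 201 ± 18.7 and 196 ± 19.7 CPM, and erythroid and megakaryocyte genes (−0.11, adjusted p = 0.672) had TFRC at 230 ± 66.5 and 219 ± 74.8 CPM. The matrix and integrin list (adjusted p = 0.694) had a median of 0.02 and a mean of −0.04, with ITGAL at 942 ± 200 and 904 ± 84.9 CPM. Leaving out 1 library made a call for the p53 list (JUN knockout replicate 2, adjusted p = 0.0295, or double knockout replicate 1, 2.05e-06), which turned to −0.053 without double knockout replicate 3. It did so for the histone list (JUN knockout replicate 2, 0.0295, or double knockout replicate 3, 0.00306), the glycolysis list (JUN knockout replicate 2, 0.0295) and the NRF2 list (double knockout replicate 2, 0.0467). The histone list also passed with no low-count filter (median −1.08, adjusted p = 2.42e-08). The usual filter kept 8 of its 33 members, so that fit added members with few reads. With all 6 libraries and the usual filter, the adjusted p with an estimated correlation was 0.666 for the p53 and histone lists, 0.611 for glycolysis and 0.588 for NRF2, and it was not computed without single libraries. MHC class II had 4 tested members and no list test, with CD74 at 374 ± 40.3 and 414 ± 69.8 CPM.

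One property of the RNA moved with the group. Transcripts annotated as retaining an intron took 5.65%, 5.86% and 5.76% of gene-matched reads in the JUN knockout libraries and 4.75%, 5.00% and 5.18% in the double knockout libraries. The means were 5.75 ± 0.1% and 4.97 ± 0.21% (SD, n = 3 each), with all 3 double knockout libraries below all 3 JUN knockout libraries (exact permutation p = 0.1, the smallest that 3 against 3 can give). It was not particular to the 41 lower DESeq2 calls. Among genes with at least 20 reads on both kinds, median log2 changes were compared between retained-intron and protein-coding transcripts. They were −0.65 against −0.39 for 28 lower calls, 0.09 against 0.54 for 11 higher calls and −0.25 against 0.01 for all such genes. When reads were summed over protein-coding transcripts alone, an alternative chosen after the data were seen, edgeR called 0 genes (577 at an unadjusted p under 0.05), DESeq2 called 52 genes (38 of them among the 71), and camera called 7 lists. The G2/M list then had a median of −0.191.

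**Figure D3:**
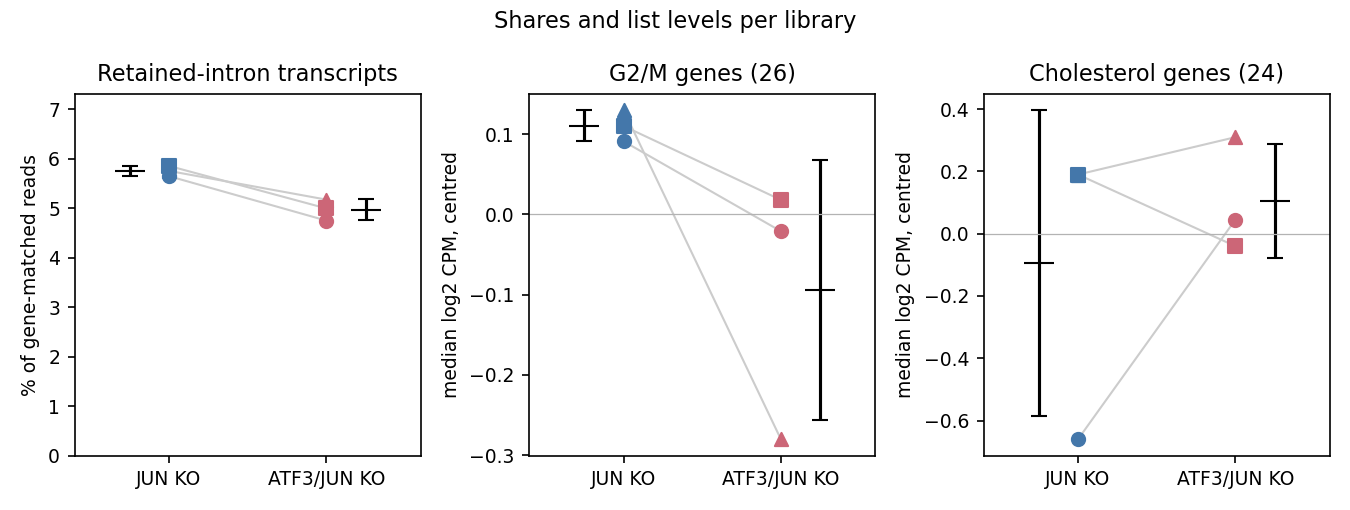
Share of gene-matched reads on transcripts annotated as retaining an intron, in percent, and the median log2 CPM of the G2/M and cholesterol lists, each gene centred on its mean over the 6 libraries (points for libraries, grey lines for same-numbered pairs, black for mean ± SD). The retained-intron share separated the groups. The G2/M level was −0.28 in double knockout replicate 3, and the cholesterol level was −0.66 in JUN knockout replicate 1.

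Libraries of 1 group differed from each other in several of the same gene lists. The level of the integrated stress response list, the median log2 CPM of its 29 tested genes after centring, was 0.45, −0.02 and −0.53 in JUN knockout replicates 1, 2 and 3 and 0.43, 0.19 and −0.51 in the double knockout. The cholesterol list was at −0.66 in JUN knockout replicate 1 and between −0.04 and 0.31 in the other 5 libraries. The p53 target list was at −0.26, 0.05 and 0.37 in double knockout replicates 1, 2 and 3. The first principal component of log2 CPM held 38.1% of the variance. It placed replicate 3 of both groups at one end and replicate 1 of both groups at the other. Between these, replicate 2 lay at 12 in the JUN knockout and −11.1 in the double knockout. The component thus did not follow the pairing for number 2. No chromosome with at least 50 genes differed between any 2 libraries by a median of more than 0.111 in size on the log2 scale.

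**Figure D4:**
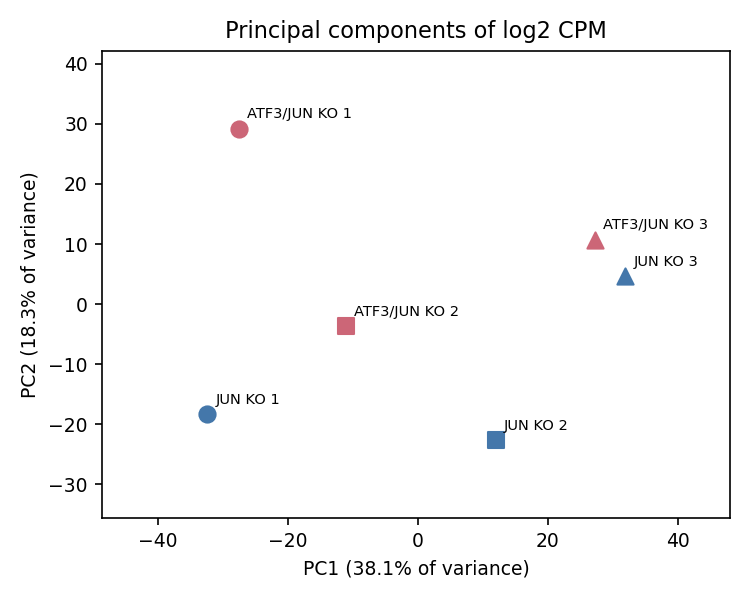
First and second principal components of log2 CPM for the 6 libraries (JUN knockout in blue, double knockout in red, shapes for replicate numbers), with the percentage of variance on each axis. The first component, with 38.1%, set replicate 3 of both groups apart from replicate 1 of both groups. On it the replicate 2 libraries lay apart, at 12 in the JUN knockout and −11.1 in the double knockout.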

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

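The test of transcripts without a match was chosen only after the data were seen. Reads on transcripts without a match in the annotation lay outside the gene comparisons, and they came to at least 3.58% of the estimated reads in every library, which is why they are listed here. Of these transcripts, 1890 had enough reads to test with the scaling of the gene table. edgeR called 0, with 91 at an unadjusted p under 0.05, a lowest adjusted p of 0.0506 and a median log2 fold change of −0.04. No other tool was run on them.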

How the results depend on the processing

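Sums over protein-coding transcripts alone, and list tests without each same-numbered pair, were chosen after the data were seen. For the number of genes called, edgeR stayed at 0 with RLE, upper-quartile or no scaling factors, a filter of 1 CPM in 3 libraries, a length offset, protein-coding genes alone, protein-coding transcripts alone, and the replicate block. It called 1 (TRIM26) with no low-count filter, and 0 to 1 when a library or a same-numbered pair was left out. The 1 was PPP1R10, without both replicates 3, named here outside the fixed rule. PPP1R10 is a gene of the major histocompatibility complex, and whether it shares reads with a copy was not tested. DESeq2 called 71, DESeq2 with the replicate block 89 (49 of them shared), limma-voom 4, and DESeq2 on protein-coding transcripts 52. The cause of the difference between tools was not tested. In simulated libraries with 200 genes changed per run, 23% of DESeq2 calls and 6.2% of edgeR calls were false. The spreads there came from edgeR's own fit. False shares also depend on how many genes change, so these do not carry over to the calls here.

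The number of lists past camera was 13, and 10 to 15 with the other scalings, limma-voom, the stricter filter, protein-coding genes alone and the replicate block (15). It was 8 with no low-count filter, 7 with the length offset and 7 with protein-coding transcripts alone. It was 0 with an estimated correlation, with or without the replicate block, 0 for fry and 0 for its mixed test, and 1 for each of these with the replicate block. It ran from 5 (without JUN knockout replicate 3) to 16 (without JUN knockout replicate 2) when libraries or pairs were left out, with 7 without double knockout replicate 1 and 8 without double knockout replicate 2. The G2/M list alone of the 13 stayed past in all 6 fits that left out 1 library. The cause of these differences was not tested. The replicate block changed no other call than those of the 2 added lists, fry and DESeq2. ATF3 stayed below 0 and short of the threshold in every alternative, from −0.14 to −0.72.

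JUN also stayed short of the threshold, and its log2 fold change ran from −0.51 to 0.06 as libraries or pairs were left out. Other ranges that crossed or touched 0 were −0.19 to 0.08 for ATF4, −0.12 to 0.24 for SLC7A5, −0.12 to 0.03 for SOD2, −0.08 to 0.23 for XAF1, −0.70 to 0.26 for LYZ, −0.13 to 0.13 for LMO4, −0.37 to 0.18 for TFRC, −0.05 to 0.26 for CD74, −0.16 to 0.13 for MCM4, −0.08 to 0.21 for TOP2A, −0.10 to 0.22 for TNFRSF10B, −0.26 to 0.15 for INSIG1, −0.09 to 0.07 for GAPDH, −0.14 to 0.21 for FTL, −0.19 to 0.15 for ITGAL and −0.26 to 0.00 for MT-CO1. The length offset turned SOD2 to 0.11, LMO4 to −0.01, TOP2A to −0.02 and INSIG1 to 0.06. Protein-coding transcripts turned XAF1 to 0.00, LMO4 to −0.04, MYB to −0.07 and GAPDH to −0.02, in edgeR and DESeq2 alike. LMO4 was at 0.00 with limma-voom and with DESeq2 and the replicate block. None of these passed on either side, and the cause was not tested.

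List medians ran, as libraries or pairs were left out and the test's direction turned at least once, from −0.179 to 0.00963 for G1/S, −0.0752 to 0.369 for cholesterol, −0.148 to 0.361 for the integrated stress response, −0.0408 to 0.0148 for NF-kB, −0.109 to 0.217 for mast cells, −0.376 to 0.0107 for erythroid genes, −0.0241 to 0.0793 for stem cells, −0.116 to 0.267 for p53, −0.0298 to 0.0954 for matrix and integrins, and −0.633 to −0.0801 for histones. With no low-count filter the direction turned for mast cell genes (median 0.0124) and lymphoid genes (−0.237). As single libraries were left out, some other medians moved without a turn of the test's direction. They ran from −0.205 to 0.223 for lymphoid genes and from 0.0189 to 0.14 for the BCL2 family. For glycolysis genes they ran from −0.00716 to 0.0557, and for NRF2 targets from 0.0189 to 0.093. Fits without 1 library or pair have fewer samples, and depth limits the genes near 1 CPM.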

Other observations

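The tests of the nonsense-mediated decay share, of single libraries, of splits and of the estimated correlation for the G2/M list, of splits by DESeq2, of 4-fold marker genes, of genes on protein-coding transcripts alone and of retained-intron transcripts gene by gene were chosen only after the result they bear on was seen.

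Reads on intron-retaining transcripts were fewer in the double knockout across many genes. Among 4014 genes with at least 20 reads on both kinds of transcript, the median log2 change was −0.25 for retained-intron transcripts and 0.01 for protein-coding ones, and the former lay below the latter in 3107. Examples picked after their values were seen were FOXM1, a transcription factor of mitosis, with retained-intron transcripts at 11.5, 13.9 and 14.5 CPM in the JUN knockout and 6.35, 5.91 and 5.58 CPM in the double knockout, and ZWINT, a kinetochore protein, at 62.6, 65.0 and 59.3 and at 27.2, 33.4 and 29.8 CPM. edgeR on retained-intron sums of 4926 genes called 0, with 780 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0832. Of the log2 fold changes, 74.6% were below 0, where the 9 other splits of the libraries had 33.2% to 67.1%. Which side of another split comes first is arbitrary, so its low shares count as much as its high ones. No other tool was run on these sums.

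What the lower retained-intron share reflects is a matter of hypotheses. A quantifier shift of reads that also took in nonsense-mediated decay transcripts was argued against. Their share differed by −0.013 percentage points and overlapped between the groups. A shift to retained-intron transcripts alone was not tested, as that share cannot show it. Genomic DNA in the JUN knockout libraries stays open: olfactory receptor genes, which these cells should hardly express, had 1.1 times the RPM (CPM without TMM scaling) in the JUN knockout (55.0 ± 5.21 against 50.1 ± 1.89), short of the ratio of 1.16 in the retained-intron share and with the groups overlapping. Separate extraction or library batches cannot be told apart from the genotypes, as labels of 0 samples name a batch, and a change in splicing or RNA decay after ATF3 loss was not tested and may also account for it. Whether it bears on the 41 lower DESeq2 calls stays open, since 20 of them and 18 of the 30 higher calls were also called on protein-coding transcripts, the 38 lower ones with a value there had a median of −0.468 (quartiles −0.731 and −0.314) against −0.529 (−0.716 and −0.411) on all transcripts, and these genes were picked for being low.

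For the lower G2/M list, the retained-intron share was argued against as the source, since the median on protein-coding transcripts was −0.191 against −0.202. A single library stays open: the highest adjusted p without each library in turn was 0.00151 (without double knockout replicate 3), which speaks against it as the whole source. Among the 10 splits of the 5 libraries left without that replicate, the real one had the lowest unadjusted p (0.00028, next 0.00156), but 10 are too few for a share under 0.05. Members that move together between libraries for any reason remain a candidate explanation for the size of the camera call, as the estimated correlation of 0.31 gave an adjusted p of 0.447. Slower cycling after ATF3 loss, or a difference in culture density, was not tested.

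Libraries differed within groups, and whole-chromosome copy number differences were argued against as the source, since the largest chromosome median was −0.111 (chromosome 18, double knockout replicates 2 and 3, bootstrap 95% interval over genes −0.157 to −0.0736), below the 0.3 in size set beforehand, while smaller segments were not tested. A shared JUN clone behind each number, to which the clone codes in the deposited file names point, was not settled by the expression values. Genes that set 1 JUN knockout library 8-fold apart were shifted most in the same-numbered double knockout for numbers 2 and 3, with intervals that included 0, but for number 1 the shift was below that of another by −3.28 on the log2 scale (95% interval −6.26 to 3.05, 6 genes). With 4-fold marker genes the differences were 0.424, 2.49 and 2.26, with an interval above 0 for number 3 alone. Whether marker genes share reads with copies was not tested. PPP1R10, of the major histocompatibility complex, was among the 8-fold markers for number 3.

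Genes at 0 in 1 group had a transcript whose group mean moved the opposite way by a similar number of reads, as near-identical copies sharing reads would give, in 2 of 5 cases (exact 95% interval 5.3% to 85.3%). Of these, RIMBP3B with RIMBP3C rested on sequence similarity. RIMBP3B had 32, 15 and 12 reads in the JUN knockout against 17.8, 4.2 and 57.8 for the partner in the double knockout. ENSG00000255432 rested on transcript length alone, with partner reads of 0, 31.3 and 40.4 in the JUN knockout and 0, 0 and 5.8 in the double knockout. That gene and its partner did not sum to like totals in the libraries numbered 1. TRIM26, MAFIP and KIAA1143P1 had no partner found. Sequences of unmatched transcripts were not searched and only single partners were sought, so copies could be missed.

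Other splits of the 6 libraries into 3 and 3 make 10 with the real one, too few for a share under 0.05. For genes called by edgeR the real value was 0 and the highest other 1706, and for retained-intron sums 0 and 2, where all 10 splits must give as many as 0, so that these counts decide nothing. For DESeq2 the values were 71 and 2547, with 2 splits giving as many. For gene lists they were 13 and 9, with 1 split. The split with 1706 and 2547 genes set JUN knockout replicate 1 and double knockout replicates 1 and 2 against the rest, which points to a structure of the samples that the groups do not follow. Among splits that part all 3 pairs, DESeq2 called 71 genes for the real one and 7, 2 and 3 for the others. These splits are fewer still than the 10, so this contrast decides nothing. It also rests on a pairing that the labels do not state.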
